A study of Homo sapiens with 15 samples.

How the data were processed

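The data were bulk MARS-seq libraries, a 3′-end RNA-seq method with UMIs and T7 amplification, of immortalized human astrocytes in which doxycycline induced mutant IDH1. Per the labels there were 15 samples: 6 without doxycycline (3 tagged b1 and 3 tagged b2), 5 at day 7 (1 of b1 and 4 of b2) and 4 at day 3 (all b2). The genotype label reads wild-type IDH1 in every sample, and no sample had doxycycline without the inducible gene.

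The authors deposited 2 tables of UMI counts, whole numbers with 1 column per library, made per the labels with bcl2fastq, cutadapt, STAR 2.4.2a and HTSeq on hg38. The day 7 table holds 15230 genes in 11 libraries (untreated and day 7, b1 and b2), and the day 3 and day 7 table holds 12575 genes in 11 b2 libraries. Both list only genes with a count of at least 6 in some library. The log2 fold changes in the same tables were computed by the authors with DESeq2 as the earlier group over the later one, and their sign was turned here. The p-values and adjusted p values were likewise deposited by the authors from DESeq2, with no model formula in the labels. The 55 columns of the authors' other per-sample values were used only to find the sign of the fold changes.

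The tables share 7 b2 libraries but not their counts. Over 11481 genes in both, each library's counts had r of 0.869 to 0.887 with its own counts in the other table, and 22.6% to 26.7% of its genes with at least 20 counts had under 2/3 of the day 7 table's count. A further 3749 genes are in the day 7 table alone and 1094 in the other alone, which has no mitochondrially encoded genes and uses older symbols (GARS for GARS1). In the day 3 and day 7 table, 2 untreated libraries carry descriptions that b1 and b2 samples share. They were taken as b2 from the set of column names, and by counts all 7 shared libraries matched themselves best. Of 1907 genes tested in both tables and called at day 7 in b2 in one of them at least, 8 had log2 changes that differed by over 1, such as KRT8 (-0.18 in the day 7 table and -1.38 in the other). ASNS, with 1 to 8 UMIs in the shared libraries of the day 7 table, was tested in the other alone. Because of these differences the planned single fit over all samples was replaced, after the tables were seen, by 1 fit per table. Day 7 against no doxycycline was read from the day 7 table, and day 3 against no doxycycline and day 7 against day 3 from the other. A single fit on the tables joined by symbol was added as an alternative after the tables were seen.

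Genes were filtered with edgeR's filterByExpr (12449 and 10586 genes tested), scaled by TMM and tested with edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3, with a batch term in the day 7 table. Benjamini-Hochberg adjustment was made over all genes tested, with a threshold of 0.05. The difference of the day 7 effect between b1 and b2 was tested as an interaction. Alternatives were DESeq2 1.42.0 and limma-voom (limma 3.58.1), other size factors, library size alone, 2 other filters, no batch term, b2 alone, thinned counts and leaving out each library. CPM values used TMM-scaled library sizes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Symbols were matched to GENCODE annotation on GRCh38 for 98.7% and 94.5% of the listed genes.

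The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 CPM and the same sign in every treated b2 sample. It also took the 3 called members with the smallest p of each list with at least 3, at most 1 of the other lists, and IDH1 always. Some genes that the rule takes are not reported here. The 44 lists were tested with limma's camera on log2 CPM (prior count 2) with its preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. They cover the IDH family, 2-hydroxyglutarate metabolism, chromatin enzymes and histones, central and lipid metabolism, mitochondria, stress and amino acid responses, inflammation and interferon, cell cycle and DNA repair, ribosomes and MYC targets, matrix, TGF-beta and YAP targets, and markers of astrocytes, neural stem cells, neurons, microglia, endothelium, fibroblasts and keratinocytes.

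Depth was 2573290 to 5567651 UMIs in the day 7 table and 1816599 to 4656705 in the other, and edgeR's common biological coefficient of variation was 0.0991 and 0.0843. Pairs of libraries of the same group and batch numbered 27, where a pair held by both tables counts once in each. Their r was 0.976 to 0.989, and their spread was 1.54 to 6.40 times that of counting alone (chi-square per degree of freedom). Tested on simulated data, the fits recovered 61.2% of 1.5-fold and 86.6% of 2-fold changes at day 7, and 53.7% and 85.1% at day 3. From day 3 to day 7 they recovered 52.2% and 85.1%, and for the difference between b1 and b2 7.46% and 38.8%. False calls were at most 11 in each. Apart from the planted changes, the simulated libraries shared a common profile with no difference between b1 and b2. These figures thus describe simpler data than the real ones.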

Results

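Gene expression was measured in immortalized human astrocytes (IHA), an established fetal cell line carrying SV40, in which doxycycline at 1 µg/ml induced a mutant IDH1, the R132H form per the series' design text. IDH1 is the cytosolic enzyme that turns isocitrate into alpha-ketoglutarate, and this mutant form makes 2-hydroxyglutarate. The 15 samples were 6 untreated, 4 at day 3 of doxycycline and 5 at day 7. The titles also carry a tag, b1 or b2, taken here as a batch: the untreated samples were 3 of b1 and 3 of b2, the day 7 samples 1 of b1 and 4 of b2, and the day 3 samples all b2. Bulk MARS-seq counts the 3′ ends of transcripts, and unique molecular identifiers (UMIs) make each count a molecule. The day 7 table held 2573290 to 5567651 UMIs per library over 15230 genes, and the table with day 3 and day 7 held 1816599 to 4656705 over 12575 genes. Over the 12449 tested genes of the day 7 table, the first principal component took 54.3% of the variance and parted b1 from b2. The second took 14.0% and parted untreated from day 7 libraries within each batch. The labels do not say that the samples of a group were separate cultures, so the p-values below measure only the spread between these samples. They give the untreated samples no day. Time in culture may thus differ between the groups compared and cannot be told apart from doxycycline.

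The first question is whether the targeted gene itself was higher with doxycycline, since the labels state that its mutant form was induced. IDH1 (chromosome 2, 208236227 to 208266074, minus strand, GRCh38) stood at 35.9 ± 0.841 CPM (scaled UMI counts) in the untreated b1 libraries (SD, n = 3) and at 31.5 ± 4.57 CPM in the untreated b2 libraries (SD, n = 3). At day 7 it stood at 43.4 CPM in the single b1 library and at 35.4 ± 4.59 CPM in b2 (SD, n = 4). The log2 change of IDH1 at day 7 was 0.22 ± 0.11 (SE) and did not pass the test (edgeR adjusted p = 0.178). Its 95% interval ended at 0.42, a 1.34-fold rise, on 90 to 210 UMIs per library. At day 3 IDH1 had a log2 change of 0.21 ± 0.14 (SE, edgeR adjusted p = 0.494), and from day 3 to day 7 one of 0.02 ± 0.13 (SE, edgeR adjusted p = 0.966). Leaving out 1 library, IDH1 ranged from 0.14 (without untreated b2-2) to 0.29 (without day 7 b2-17, edgeR adjusted p = 0.0543) at day 7, and from 0.06 (without untreated b2-2) to 0.28 at day 3. A 3′ tag counts only transcripts that end as the annotated gene does, and the 3′ end of the induced transcript is not given in the sources used here, so these counts do not check the induction.

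The series names day 7 against no doxycycline as its comparison, and at day 7 the cytokine IL1B and several CXCL chemokines rose and the collagen chain COL1A2 fell. PPIF, cyclophilin D of the mitochondrial matrix (chromosome 10, 79347469 to 79355337), rose 3.47-fold, from 194 ± 11.7 to 722 ± 27.0 CPM in b2 (SD, n = 3 and n = 4) and from 278 ± 15.4 (SD, n = 3) to 829 CPM in b1. IL1B rose by 1.90 ± 0.13 on the log2 scale (SE), CXCL3, a neutrophil chemokine, by 2.49 ± 0.26, and ANGPTL4, an inhibitor of lipoprotein lipase, by 2.25 ± 0.23. CXCL1, CXCL2 and CXCL5, of the same chemokine family, rose by 1.79 ± 0.29, 1.66 ± 0.31 and 1.95 ± 0.21. COL1A2 (chromosome 7, 94394561 to 94431232) fell 3.60-fold, from 322 ± 15.3 to 84.3 ± 4.48 CPM in b2 (SD, n = 3 and n = 4) and from 200 ± 22.6 (SD, n = 3) to 66.2 CPM in b1. Among genes with a mean of at least 20 CPM, other large falls were PCK2 (-1.45 ± 0.27), the mitochondrial PEP carboxykinase, CA9 (-1.35 ± 0.14), a carbonic anhydrase raised by hypoxia, TXNIP (-1.23 ± 0.09), an inhibitor of thioredoxin, and SERPING1 (-1.19 ± 0.13), the C1 inhibitor. CSF2, a myeloid growth factor, rose by 1.38 ± 0.25, and by 0.84 without the b1 day 7 library. With the b2 counts of the other table, which hold no b1 library, CXCL1 rose by 1.19 and CSF2 by 0.81.

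**Figure D1:**
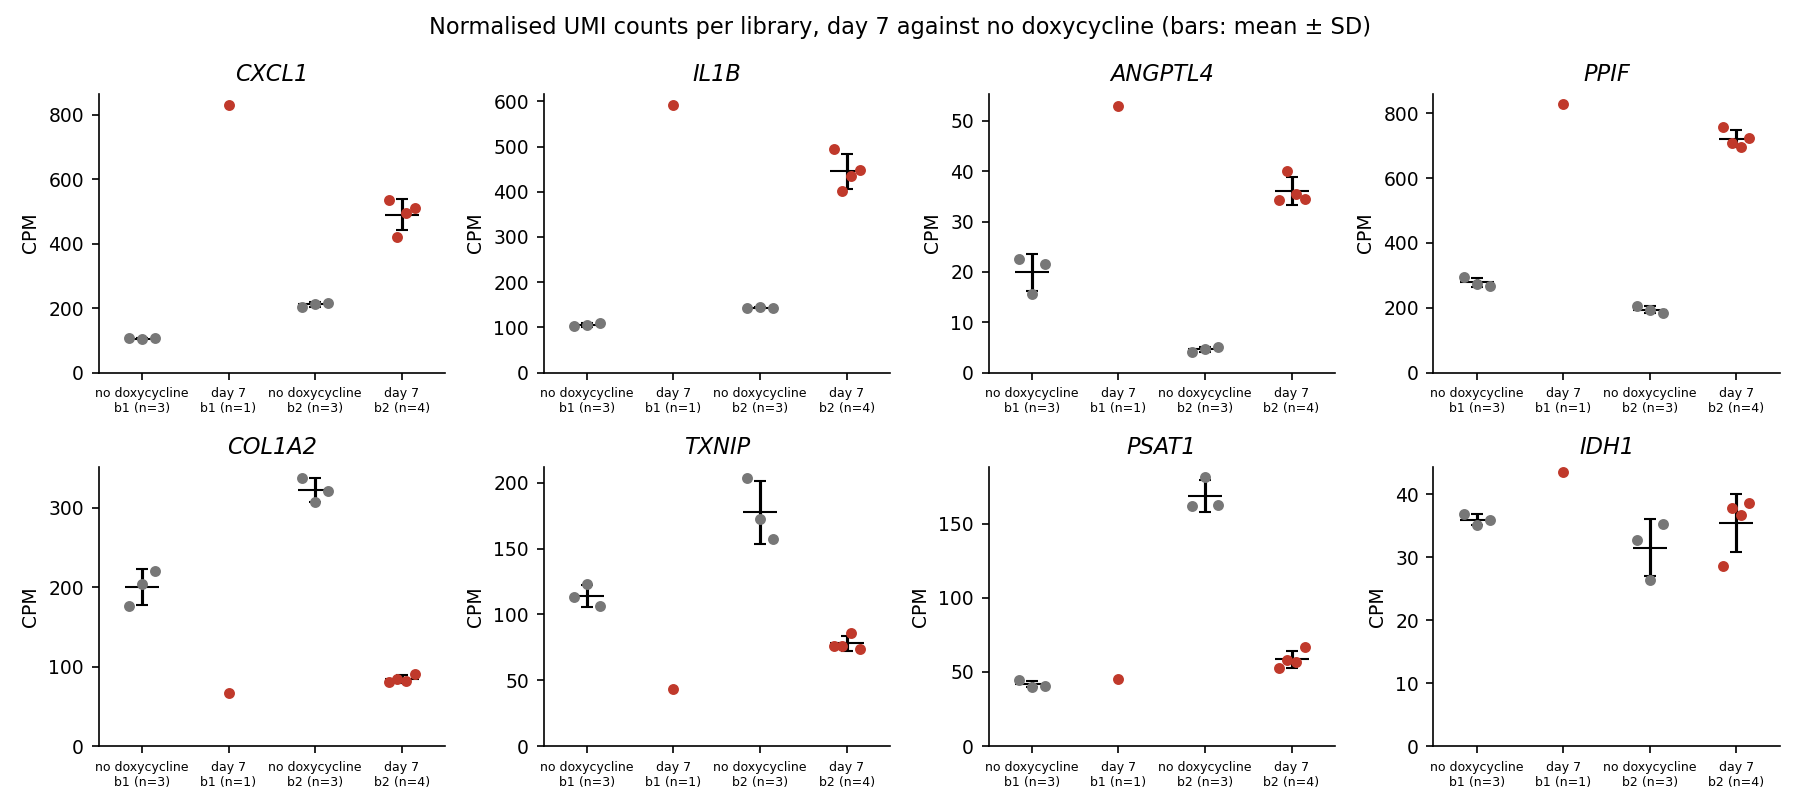
CPM of 8 genes in each library of the day 7 table, by batch and treatment, as points with the mean and SD of each group of more than 1 library. PPIF lay at 722 CPM at day 7 and 194 CPM without doxycycline in b2, COL1A2 at 84.3 and 322 CPM, and IDH1 at 35.4 and 31.5 CPM.

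In all, edgeR's quasi-likelihood test with a batch term called 1955 of 12449 genes at day 7 (Benjamini-Hochberg adjusted p under 0.05), 1049 up and 906 down, of which 76 rose and 100 fell at least 2-fold. With counts scaled by library size alone, the split of calls turned to 667 up and 1429 down, and all genes' median log2 change moved from -0.02 to -0.09. The CXCL genes, the metallothioneins, the HLA genes, IFITM2 and IFITM3, and the ribosomal protein genes have close relatives or pseudogenes, so counts may be split among them and their values are uncertain.

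Among the fixed lists, 12 of 22 NF-kB and inflammatory genes rose at day 7, with LIF (0.89 ± 0.08) beside the chemokines, and VCAM1, an adhesion molecule, fell (-0.74 ± 0.12). That list's limma camera call (adjusted p = 1.5e-07) had an adjusted p of 0.295 with an estimated correlation. Of 26 immediate early genes 14 rose, among them DUSP1 (1.01 ± 0.10), DUSP5 (0.80 ± 0.12) and IER3 (0.68 ± 0.07), while BTG2 (-0.69 ± 0.21) and JUND (-0.30 ± 0.10) fell (limma camera adjusted p = 1.6e-05, and 0.0254 with an estimated correlation). Of 28 MYC targets and ribosome biogenesis genes 12 rose, led by ODC1 (0.54 ± 0.06), which makes polyamines, NOP56 (0.47 ± 0.06) and NOP16 (0.58 ± 0.09), and CAD fell (limma camera adjusted p = 4.1e-07, and 0.0254 with an estimated correlation). Of 41 ribosomal protein genes 15 rose, such as RPL11 (0.28 ± 0.07; limma camera adjusted p = 4.0e-07, and adjusted p = 0.278 with an estimated correlation).

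Some transcripts of the mitochondrion's own machinery also rose at day 7. Of 13 mitochondrially encoded genes 5 rose: MT-ND3 (1.26 ± 0.19), MT-CYB (0.77 ± 0.14), MT-ND1 (0.68 ± 0.12), MT-ND2 (0.60 ± 0.16) and MT-CO3 (0.25 ± 0.08). Without the batch term MT-CYB had a log2 change of -0.18, since its level differed between the batches, from 309 ± 39.9 CPM in untreated b1 to 33.5 ± 3.40 CPM in untreated b2 (SD, n = 3 each). Of 44 nuclear-encoded OXPHOS subunits 8 rose, such as ATP5MC1 (0.41 ± 0.07), ATP5PF (0.40 ± 0.08) and NDUFB10 (0.31 ± 0.06), and of 29 mitochondrial ribosome and translation genes 10 rose, such as MRPL3 (0.34 ± 0.06) and MRPS12 (0.35 ± 0.07). The limma camera adjusted p of these lists was 0.000891, 0.000143 and 0.000107, and with an estimated correlation the adjusted p was 0.139, 0.107 and 0.107. Mitochondrially encoded genes took 1.23% to 1.58% of UMIs in untreated and 1.58% to 1.79% in day 7 libraries.

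At day 7 the lists of the amino acid response, interferon, collagen and mitosis were called lower with camera's preset correlation and not with an estimated one. limma's fry, which does not compare a list with the other genes, also called them lower (adjusted p = 0.00504, 0.000279, 4.2e-05 and 0.00504 in that order). The limma camera adjusted p was 1.5e-07, 0.000427, 7.5e-05 and 0.05 in that order, the last just under the threshold, and 0.295, 0.0583, 0.0527 and 0.244 with an estimated correlation. With the b2 libraries alone the G2/M list had a limma camera adjusted p of 0.229. Of 29 amino acid response genes and targets of the transcription factor ATF4, 16 fell, among them NUPR1 (-2.30 ± 0.25), ALDH1L2 (-1.87 ± 0.23), which works in folate metabolism, PSAT1 (-1.17 ± 0.24), of serine synthesis, and GARS1 (-0.68 ± 0.07), the glycyl-tRNA synthetase. Of 21 type I interferon response genes 8 fell, such as IFITM2 (-1.39 ± 0.15) and IFITM3 (-0.74 ± 0.12), and ISG20 rose (0.72 ± 0.15). Of 21 collagen and matrix genes 9 fell, COL8A1 (-1.04 ± 0.10) and the proteoglycan BGN (-0.89 ± 0.08) with COL1A2, and TNC rose (0.52 ± 0.07). Of 35 G2/M genes 9 fell, such as KIF23 (-0.34 ± 0.07), and CDC20 (0.35 ± 0.06) and PLK1 (0.24 ± 0.07) rose. With the b2 counts of the other table KIF23 fell by 0.21 on the log2 scale and ISG20 rose by 0.46.

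The series title names histone acetylation and chromatin, so the enzymes that write and erase these marks were read as lists. At day 7 KAT2A, a histone acetyltransferase, rose (0.48 ± 0.09) and KAT6B fell (-0.39 ± 0.11), of 17 acetyltransferase genes. HDAC6 (-0.51 ± 0.10), which mainly deacetylates tubulin, and HDAC10 (-0.62 ± 0.15) fell, of 20 deacetylase genes. Of 26 histone lysine methyltransferases 6 fell, among them NSD1 (-0.46 ± 0.09), which methylates H3K36, and SETD7 rose (0.35 ± 0.08). KMT2A, also among the 6, lost its call with the b2 counts of the other table and when both tables were joined in one fit. Of the 22 genes on the histone lysine demethylase list, JMJD6, not an established lysine demethylase, rose (0.37 ± 0.09) and KDM5B fell (-0.45 ± 0.08). KDM5B did not pass with the b2 counts of the other table (-0.37, edgeR adjusted p = 0.123). Of the 6 TET and DNA methyltransferase genes edgeR and DESeq2 called 0 and limma called 1, and 1 had an unadjusted p under 0.05. None of these 5 lists was called by limma camera at day 7 (adjusted p from 0.298 to 0.943). limma's fry, which does not compare a list with the other genes, called the methyltransferase, acetyltransferase and deacetylase lists lower (adjusted p = 0.0123, 0.0301 and 0.0386). Over the 5 lists, edgeR called 0 of 80 genes at day 3, as did DESeq2 and limma, with 12 at an unadjusted p under 0.05. There limma's fry called the demethylase and acetyltransferase lists higher (adjusted p = 0.00496 and 0.0238). The acetyltransferase call was opposite to that at day 7, which came from the other counts and held b1 too. Tested directly from day 3 to day 7 in b2, the acetyltransferase list was not called (limma fry adjusted p = 0.254, limma camera adjusted p = 0.413). From day 3 to day 7 edgeR called 3 of the 80: KDM4B (-0.44 ± 0.10) and HDAC6 (-0.37 ± 0.10) fell and SETD7 (0.32 ± 0.09) rose. HDAC6 did not pass without the day 3 library b2-9 or b2-12 or the day 7 library b2-18 (edgeR adjusted p from 0.0703 to 0.111), nor SETD7 without b2-9, b2-10 or b2-11 of day 3 or b2-19 or b2-20 of day 7 (0.0524 to 0.0657). HDAC6 also did not pass with DESeq2, nor when both tables were joined in one fit (edgeR adjusted p = 0.124).

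Other lists had called members at day 7 and were not called by camera. Of 23 TGF-beta and YAP targets 7 rose, among them ID1 (0.82 ± 0.07), ID3 (0.65 ± 0.06) and TGFB1 (0.62 ± 0.07). The 8 that fell included TAGLN (-0.77 ± 0.07), of smooth muscle, and CCN1 (-0.45 ± 0.07). Of 20 unfolded protein response genes 7 rose, such as CALR (0.32 ± 0.06) and MANF (0.38 ± 0.09), and CREB3L2 and XBP1 fell. Of 15 heat shock proteins 6 rose, such as HSPE1 (0.46 ± 0.07), and CRYAB (-2.30 ± 0.17) and HSPB1 (-0.40 ± 0.07) fell (limma camera adjusted p = 0.0524 for each list). Of 21 hypoxia targets 4 rose, VEGFA (0.74 ± 0.08), PFKFB4, ADM and SLC2A1, and 5 fell, CA9, LOX, PDK1, BNIP3L (-0.47 ± 0.08) and MXI1. Of 19 glycolysis genes SLC2A1 and PFKFB3 rose and ALDOC (-0.83 ± 0.10), PFKL, PGK1 and TPI1 (-0.38 ± 0.07) fell. Of 23 p53 targets CDKN1A (0.33 ± 0.07), AEN, TP53I3 and TNFRSF10B rose and BTG2, GADD45B and GDF15 fell. With the b2 counts of the other table CDKN1A (0.22), AEN and TP53I3 did not pass (edgeR adjusted p = 0.0545, 0.0845 and 0.164). Of 20 apoptosis regulators BID (0.41 ± 0.07), BCL2A1 and BIRC2 (0.41 ± 0.13) rose, BID by 0.67 and BIRC2 by 0.63 with those counts. Of 23 NRF2 and redox genes HMOX1 (0.95 ± 0.11) and SOD2 (0.94 ± 0.09) rose and the cystine transporter SLC7A11 (-1.86 ± 0.40) fell. Of 37 DNA replication genes RPA2 rose and TK1 (-0.33 ± 0.06), CDT1 and RFC4 fell. Of 27 DNA repair genes FANCD2 fell.

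Among the metabolic lists at day 7, PYCR1 (-0.58 ± 0.09), of proline synthesis, GOT1 and GPT2 fell and GOT2 rose of 15 branched-chain amino acid and glutamine genes, and PHGDH (-0.57 ± 0.11) fell of 7 genes of 2-hydroxyglutarate metabolism. Of 15 TCA cycle genes SUCLG2 fell (-0.38 ± 0.10), of 5 genes of the IDH family IDH3B rose, of 16 acetyl-CoA supply genes ACO1 rose and PDK1 and SLC25A1 fell, and of 9 metallothioneins MT1E rose. Of 24 cholesterol genes LSS rose and 2 fell, FDPS among them, and of 12 fatty acid synthesis genes ELOVL1 (0.34 ± 0.07) rose and SCD (-0.53 ± 0.13) fell. Of 15 histone genes H2BC12 rose and 2 fell, among them the linker histone H1-10 (-0.40 ± 0.08), with H2BC12 uncertain because of its close relatives. Of 19 collagen hydroxylation and crosslinking genes CRTAP rose and LOX, LOXL1 (-0.65 ± 0.08) and LOXL3 fell, although LOX had an edgeR adjusted p of 0.213 with the b2 counts of the other table. Among cell type markers, ID3, HES1 (0.52 ± 0.08), CD44 and SOX9 rose and ALDOC and CLU fell of 14 for astrocytes. CSPG4 and PAX6 fell of 9 for neural stem cells, CSPG4 (-0.40 ± 0.09) and THY1 fell of 9 for fibroblasts and pericytes, EGFL7 rose and TIE1 (-0.78 ± 0.16) fell of 4 for endothelium, and CSF1R rose of 2 for microglia. Of 9 keratinocyte markers LAMB3 (0.45 ± 0.10), KRT7, KRT80 and KRT81 rose and KRT8, KRT17 and KRT19 (-0.93 ± 0.16) fell. edgeR, DESeq2 and limma each called 0 of 3 neuron markers and 0 of 14 antigen presentation genes, with 0 and 5 at an unadjusted p under 0.05. The antigen presentation list had a median log2 change of -0.33 in b2 and 0.29 in b1, with 1 day 7 library in b1, so its day 7 values average opposite signs. The lists of these paragraphs had limma camera adjusted p from 0.0524 to 0.949, and at day 3 and from day 3 to day 7 the lists not described here as called had 0.058 to 0.84 and 0.0688 to 0.931. Of these lists, limma's fry called the unfolded protein response, NRF2 and redox and IDH family lists higher at day 7. It called the cholesterol, acetyl-CoA supply, branched-chain amino acid, neural stem cell and fibroblast lists lower (adjusted p from 0.00143 to 0.0271 over these lists).

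Some of these day 7 calls were lost when 1 library was left out. Only genes that the fixed rule took were checked in this way, so the other members named above are not known to hold. Among those, KRT8 had a log2 change of -0.18 in the b2 libraries of the day 7 table and -1.38 with the b2 counts of the other. Without the b1 day 7 library b1-13, AEN, TP53I3 and RFC4 did not pass (edgeR adjusted p = 0.0563, 0.0984 and 0.0801), nor GOT1 without b1-13 or b2-1 (0.0617 and 0.0772), KRT17 without b2-1 (0.0616) or CSF1R without b2-2 (0.0686). IDH3B did not pass without b2-1, b2-2, b2-4 or b2-20 (edgeR adjusted p from 0.0537 to 0.0675), FANCD2 without b2-1, b2-2, b2-17, b2-18 or b2-20 (0.0527 to 0.124), LSS without b1-13, b2-1 or b2-4 (0.0595 to 0.192) and GOT2 without b2-1, b2-2, b2-4, b2-18 or b2-20 (0.0507 to 0.102). BIRC2 did not pass without b1-2, b2-1, b2-2, b2-4, b2-18, b2-19 or b2-20 (edgeR adjusted p from 0.0514 to 0.133), and ACO1 without b1-2, b1-3, b2-1, b2-2, b1-13, b2-17 or b2-20 (0.0542 to 0.133). PDK1 (-0.37 without b1-13), FDPS, MT1E (0.18 without b1-13) and SLC25A1 (-0.39 without b1-13) passed without few of the 11 libraries: PDK1 without b1-3, b2-4 or b2-19, FDPS without b2-1 or b2-20, MT1E without b2-2 or b2-19, and SLC25A1 without b1-2, b1-3 or b1-13. With the b2 counts of the other table PDK1, ACO1, LSS, FDPS, MT1E and RFC4 did not pass (edgeR adjusted p from 0.0546 to 0.309) and SLC25A1 fell by 0.42 on the log2 scale. FANCD2 did not pass when both tables were joined in one fit (edgeR adjusted p = 0.0672).

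The 2 batches were then compared, because the day 7 value of a gene is a mean over b1 and b2. CXCL1 rose by 2.97 ± 0.11 in b1, from 106 ± 2.30 to 830 CPM, and by 1.22 ± 0.08 in b2, from 212 ± 6.74 to 490 ± 49.6 CPM (SD, n = 3, n = 1, n = 3 and n = 4). CXCL3 rose by 3.69 ± 0.26 and 2.02 ± 0.16, IL1B by 2.49 ± 0.10 and 1.64 ± 0.08, and ANGPTL4, the other way, by 1.39 ± 0.19 in b1 and 2.96 ± 0.17 in b2. PSAT1 had a log2 change of 0.12 ± 0.17 in b1 and fell by 1.52 ± 0.09 on the log2 scale in b2, and PCK2 had 0.01 ± 0.23 in b1 and fell by 1.83 ± 0.12 on the log2 scale in b2. PPIF (1.58 and 1.90) and COL1A2 (-1.59 and -1.92) had effects whose difference did not pass the test (edgeR adjusted p = 0.183 and 0.318).

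**Figure D2:**
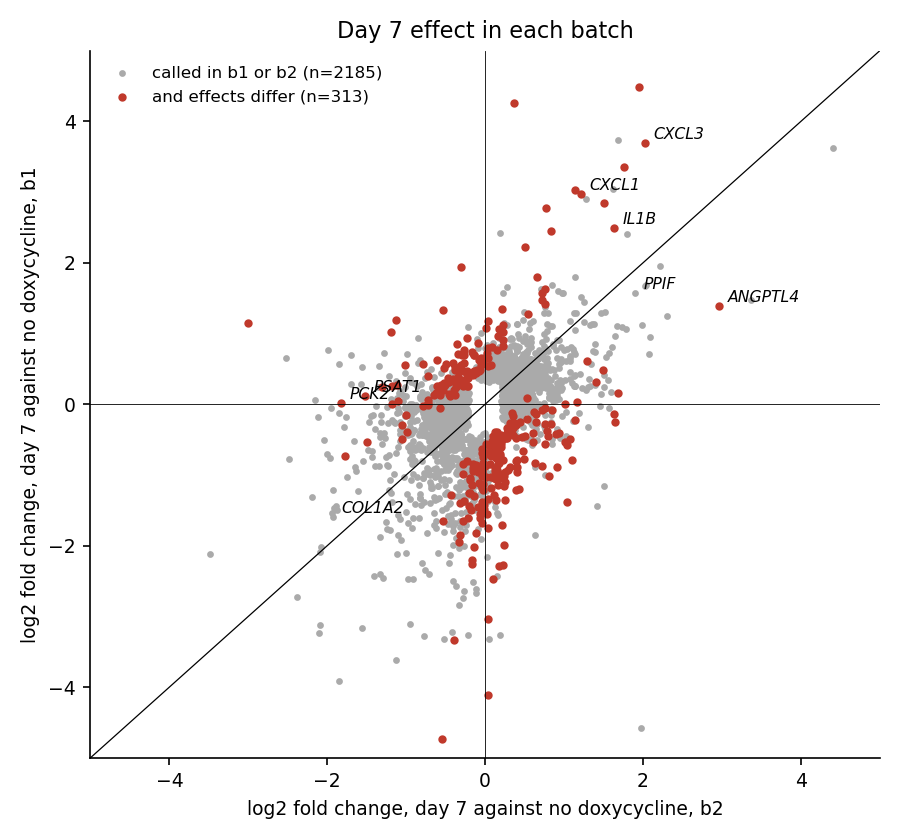
Log2 fold change at day 7 in b2 (x axis) and in b1 (y axis) of each gene called in either batch, with the line of equal change. The 313 red genes also had effects that differed between the batches, such as CXCL1 at 1.22 in b2 and 2.97 in b1, and 10 genes lie outside the axes.

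The edgeR interaction of batch and day 7 called 326 of 13371 genes, 190 with a higher value in b2 and 136 with a lower one, and with library size alone 272 and 100. With limma-voom the balance turned, to 91 higher and 114 lower. The count was 195 without the untreated library b1-2, 216 without b1-3, 205 without b2-2 and 687 without the day 7 library b2-17. Of 1913 genes called at day 7 in b2, 1439 (75.2%) had the same sign in b1. Over these genes the slope of the b1 on the b2 effect was 0.556 (r = 0.549). By list, the day 7 effect was lower in b2 for NF-kB and inflammatory genes (11 members lower), amino acid response genes (7 members lower) and antigen presentation (6 members lower), and higher for hypoxia targets. The limma camera adjusted p was 1.5e-13, 2.0e-09, 8.9e-06 and 0.00101 in that order, and 0.0393 for each with an estimated correlation. Metallothioneins (3 members lower in b2), heat shock proteins (3 higher) and p53 targets (2 higher, with a median difference of -0.38) were called with the preset correlation alone (limma camera adjusted p = 0.00278, 0.00522 and 0.0196, and 0.062, 0.062 and 0.258 with an estimated correlation). Since b1 holds 1 day 7 library, its spread was assumed to be that of the other groups. The differences between the batches, by gene and by list, cannot be told apart from noise of that library.

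Against the untreated b2 libraries, whose day of harvest is not given, the day 3 libraries had lower amino acid response and higher hypoxia target transcripts. ASNS, asparagine synthetase (chromosome 7, 97852118 to 97872542), fell 3.63-fold, from 127 ± 7.73 to 35.1 ± 1.87 CPM (SD, n = 3 and n = 4), and PSAT1 fell 3.17-fold, from 200 ± 13.1 to 63.4 ± 3.13 CPM. PCK2 (-1.49 ± 0.11), TRIB3 (-1.10 ± 0.13), a pseudokinase induced by ATF4, GARS (453 ± 16.1 to 226 ± 9.94 CPM), CBS (-0.85 ± 0.09), of cysteine synthesis, and PHGDH (-0.74 ± 0.07), the first enzyme of serine synthesis, fell too. NDRG1, a hypoxia target, rose 3.20-fold, from 71.0 ± 10.4 to 225 ± 36.7 CPM, PPIF rose 2.52-fold, from 240 ± 14.6 to 606 ± 21.5 CPM, and ANGPTL4 rose 3.32-fold (log2 1.73, and 1.14 when both tables were joined in one fit). Among genes with a mean of at least 20 CPM, other large rises were DUSP2 (1.37 ± 0.17), a MAP kinase phosphatase, INHBB (1.24 ± 0.15), an activin subunit, SLC22A23 (1.22 ± 0.16), RDH10 (1.08 ± 0.16), of retinoid metabolism, and SLCO4A1 (0.97 ± 0.17). The day 7 table gave ASNS 1 to 8 UMIs in the b2 libraries that both tables hold, too few to be tested. The table used here gave 79 to 597, so the ASNS values rest on 1 table. COL1A2 (-0.74 ± 0.07) and SERPING1 (-0.78 ± 0.10) had fallen by day 3.

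By list, 19 of 30 amino acid response genes fell at day 3 (limma camera adjusted p = 1.9e-24, and 0.000682 with an estimated correlation), with a median log2 change of -0.57. Of 21 hypoxia targets 6 rose, among them NDRG1, BNIP3 (0.51 ± 0.07), of mitophagy, and the glucose transporter SLC2A1 (0.54 ± 0.07; limma camera adjusted p = 7.2e-09, and 0.0038 with an estimated correlation). Of 19 glycolysis genes 4 rose: SLC2A1, GPI (0.34 ± 0.08), ENO2 (0.36 ± 0.08) and PFKFB3 (0.41 ± 0.10). ENO2 did not pass without the untreated library b2-1 (edgeR adjusted p = 0.0533), nor PFKFB3 without b2-4 (edgeR adjusted p = 0.0619). Of 21 NF-kB and inflammatory genes 6 rose, such as IL11 (0.60 ± 0.10), and VCAM1 fell (-0.60 ± 0.15). Of 39 ribosomal protein genes RPL7A, RPL11, RPL30 and RPS12 rose, of 27 MYC targets HSPD1, a mitochondrial chaperone, rose (0.45 ± 0.08), and of 9 metallothioneins MT1E (-0.44 ± 0.08) and MT2A (-0.31 ± 0.08) fell. When both tables were joined in one fit, PFKFB3, HSPD1 and MT1E did not pass (edgeR adjusted p = 0.111, 0.0591 and 0.396), with MT1E at -0.29. The limma camera adjusted p of the lists from glycolysis to metallothioneins was 3.2e-05, 0.024, 5.8e-06, 0.0125 and 0.0116, and with an estimated correlation the adjusted p was 0.203, 0.281, 0.279, 0.11 and 0.11. Of the ribosomal protein genes, RPL11 did not pass without any 1 of the untreated or day 3 libraries (edgeR adjusted p from 0.0605 to 0.209), RPS12 without any 1 of these or the day 7 library b2-20 (0.0564 to 0.147), and RPL7A without b2-1, b2-2, b2-9 or b2-12 (0.0909 to 0.166).

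**Figure D3:**
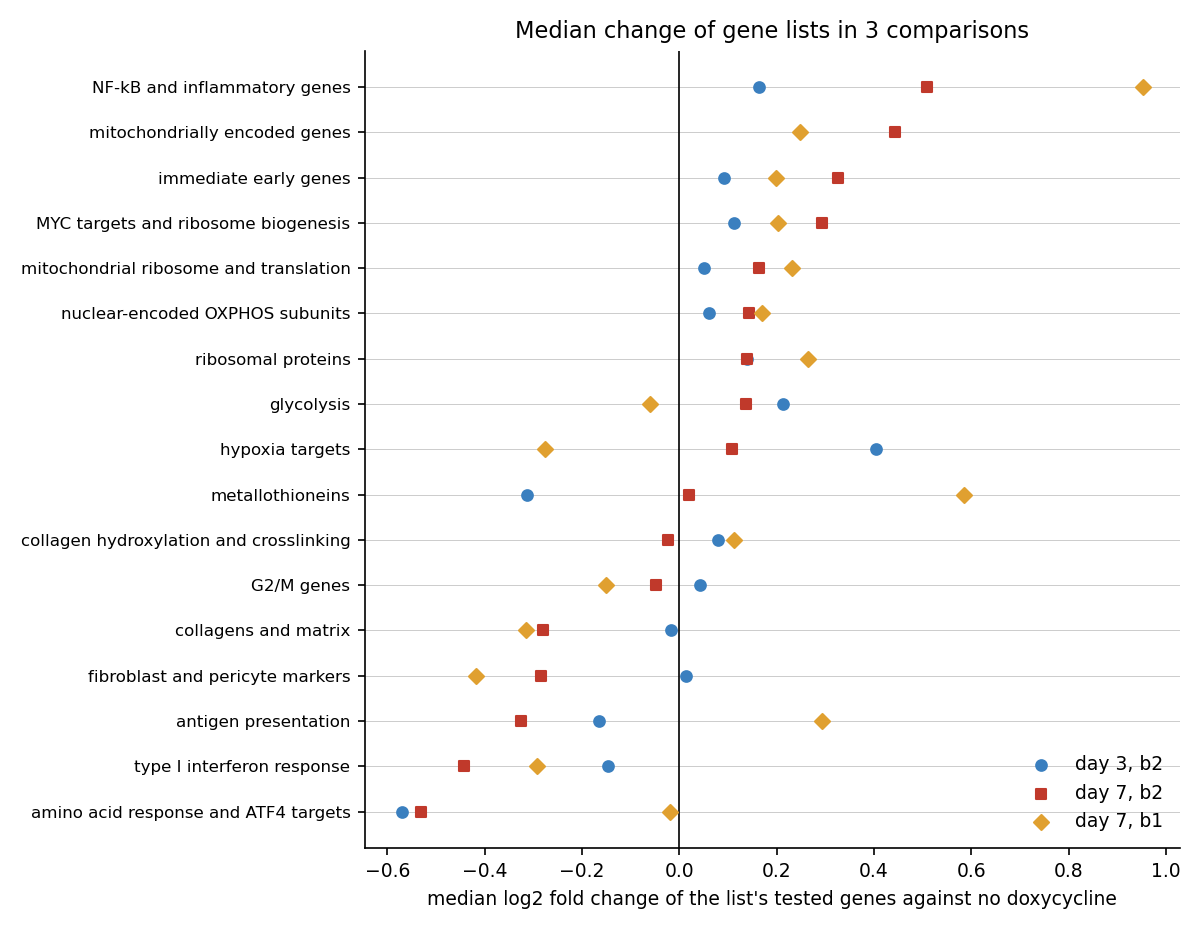
Median log2 fold change against no doxycycline (x axis) of the tested genes of each list called by camera in any comparison, at day 3 in b2 (circles), day 7 in b2 (squares) and day 7 in b1 (diamonds). The amino acid response list lay at -0.57, -0.53 and -0.02, and the NF-kB and inflammatory list at 0.16, 0.51 and 0.95.

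edgeR called 372 of 10586 genes at day 3, 195 up and 177 down, of which 16 rose and 25 fell at least 2-fold. With library size alone the split was 129 up and 240 down. The count was 213, 191 and 207 without the untreated libraries b2-1, b2-2 and b2-4, 229 and 228 without the day 3 libraries b2-10 and b2-12, and 578 without the day 7 library b2-17, which enters through the shared estimate of spread.

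From day 3 to day 7, tested directly in b2, 10 of 21 NF-kB and inflammatory genes rose and TNFAIP2 fell (limma camera adjusted p = 0.000475, and adjusted p = 0.118 with an estimated correlation), and 9 of 20 collagen and matrix genes fell. CXCL5 (chromosome 4, 73995642 to 73998779) rose 2.93-fold, from 27.6 ± 3.49 to 80.0 ± 6.50 CPM (SD, n = 4 each), against 28.1 ± 3.67 CPM in untreated cells (SD, n = 3). IL1B (2.39-fold, from 224 ± 5.17 to 536 ± 47.9 CPM), CSF2 (1.20 ± 0.13), ANGPTL4 (1.20 ± 0.13), CXCL3 (1.17 ± 0.15), ALDH1A3 (1.08 ± 0.09), which makes retinoic acid, G0S2 (1.08 ± 0.06), an inhibitor of lipolysis, and STC1 (0.97 ± 0.12) were, with CXCL5, the largest rises among genes with a mean of at least 20 CPM. CA9 fell 3.04-fold, from 37.8 ± 9.09 to 12.2 ± 2.27 CPM, and COL1A2 fell 2.28-fold, from 217 ± 11.2 to 95.1 ± 3.38 CPM. TNFAIP2 (-1.23 ± 0.13), MFAP4 (-1.22 ± 0.13), of elastic fibres, NNMT (-1.05 ± 0.08), a nicotinamide methyltransferase, BGN (274 ± 14.3 to 137 ± 7.12 CPM) and ALDOC (-0.96 ± 0.10), a brain aldolase, were among the other large falls.

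**Figure D4:**
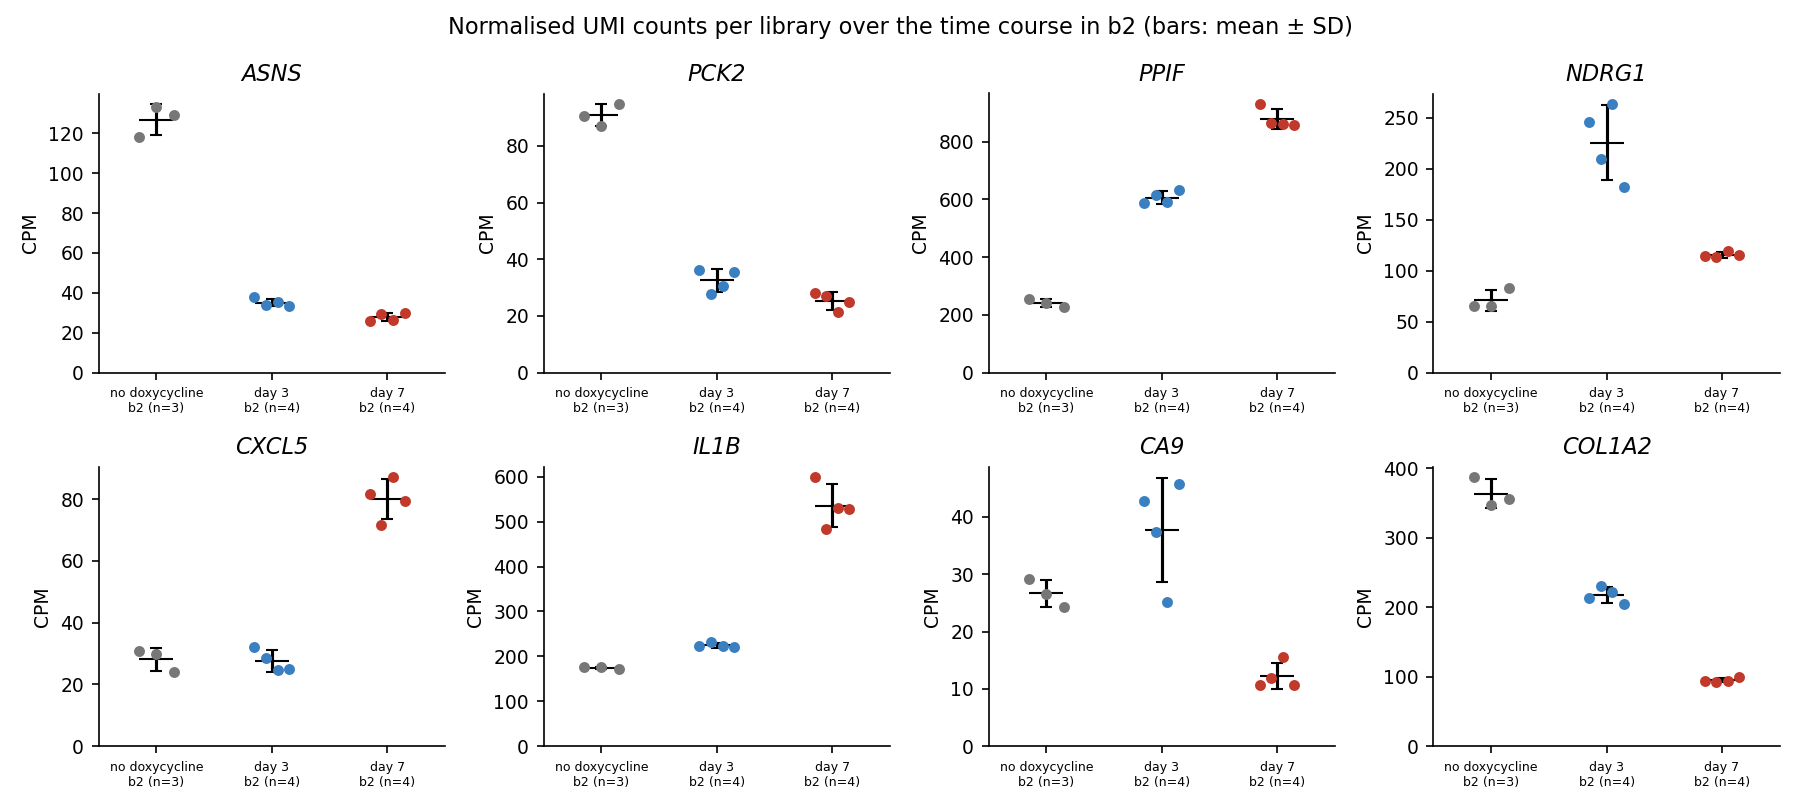
CPM of 8 genes in each b2 library without doxycycline, at day 3 and at day 7, as points with the mean and SD of each group. ASNS, too low in the day 7 table to be tested, lay at 127, 35.1 and 27.8 CPM, NDRG1 at 71.0, 225 and 116 CPM, and CXCL5 at 28.1, 27.6 and 80.0 CPM in the 3 groups.

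The fall of the collagen and matrix list held with an estimated correlation (limma camera adjusted p = 4.4e-07, and 0.0221). Of 21 hypoxia targets 5 fell, CA9, NDRG1 (-0.96 ± 0.10), MXI1 (-0.72 ± 0.11), P4HA1 and BNIP3 (-0.41 ± 0.06), and ADM rose (0.30 ± 0.09; limma camera adjusted p = 0.000475, and 0.0299 with an estimated correlation). NDRG1, MXI1 and BNIP3 had risen at day 3, where CA9 (0.49 ± 0.16) and P4HA1 (0.45 ± 0.13) had not passed (edgeR adjusted p = 0.1 and 0.058). Both comparisons use the day 3 libraries, which favours opposite signs. Of 17 type I interferon response genes IFITM2 (-0.96 ± 0.17), IFITM3 (-0.66 ± 0.07) and PARP14 (-0.62 ± 0.13) fell (limma camera adjusted p = 0.000585, and 0.0299 with an estimated correlation). Of 27 MYC targets 4 rose, ODC1 (0.50 ± 0.06), NOP16 (0.44 ± 0.07), NOP56 (0.29 ± 0.06) and UTP20 (0.38 ± 0.11; limma camera adjusted p = 1.2e-05, and 0.0208 with an estimated correlation). Of 13 antigen presentation genes 4 fell, among them HLA-B (-0.47 ± 0.07), HLA-C (-0.30 ± 0.07) and HLA-E (-0.28 ± 0.06). That list's limma camera adjusted p was 0.000585, and adjusted p = 0.0835 with an estimated correlation. HLA-B and HLA-E did not pass when both tables were joined in one fit (edgeR adjusted p = 0.238 and 0.113).

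A further 7 lists were called from day 3 to day 7 by limma camera with its preset correlation and lost the call with an estimated one. Of 19 glycolysis genes 6 fell, such as ALDOC, PGK1 (-0.35 ± 0.07) and TPI1 (-0.32 ± 0.06; adjusted p = 0.000645, and 0.208 with an estimated correlation). Of 26 immediate early genes DUSP6 (0.73 ± 0.10), SPRY4, FOSL1, DUSP1 and IER3 rose and JUNB (-0.50 ± 0.09), JUND and ATF3 fell (adjusted p = 0.0443, and 0.113 with an estimated correlation). With library size alone that list's limma camera adjusted p was 0.0531. Of 34 G2/M genes CDC25C (-0.49 ± 0.11), KIF20A (-0.30 ± 0.07), CDC25B and MKI67 fell (adjusted p = 0.00164, and 0.0943 with an estimated correlation). Of 19 collagen hydroxylation and crosslinking genes LOXL1 (-0.43 ± 0.07), P4HA1 (-0.52 ± 0.12) and LOXL3 (-0.52 ± 0.13) fell (adjusted p = 0.00183, and 0.0943 with an estimated correlation). Of 9 metallothioneins MT1E (0.60 ± 0.08), MT1A and MT2A rose (adjusted p = 0.0173, and 0.0943 with an estimated correlation). Of 29 mitochondrial ribosome genes MRPL15 (0.31 ± 0.07), MRPS12, MRPL3 and MRPS2 rose (adjusted p = 0.00284, and 0.062 with an estimated correlation). Of 7 fibroblast and pericyte markers CSPG4 (-0.39 ± 0.08) and NOTCH3 (-0.68 ± 0.15) fell (adjusted p = 0.00732, and 0.136 with an estimated correlation). Some of these genes lost the edgeR call when 1 library was left out: ATF3 without b2-9, b2-10, b2-11, b2-19 or b2-20 (adjusted p from 0.0672 to 0.118), MRPS2 without b2-10, b2-11, b2-12 or b2-18 (0.0605 to 0.104) and LOXL3 without b2-11 or b2-20 (0.0627 and 0.0574). MKI67 lost it without b2-9 (edgeR adjusted p = 0.0759), MT2A without b2-10 (0.091), and MT1A without any 1 library but b2-12 (0.0522 to 0.144). MT2A also lost it when both tables were joined in one fit (edgeR adjusted p = 0.133).

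In total edgeR called 537 of 10586 genes between day 3 and day 7, 292 up and 245 down, of which 30 rose and 24 fell at least 2-fold. Among the lists, camera with its preset correlation called 11 at day 7, 7 at day 3 and 13 between them. With an estimated correlation 2, 2 and 4 calls held: immediate early genes and MYC targets at day 7, amino acid response and hypoxia at day 3, and collagens, hypoxia, interferon and MYC targets between them. Adjusted over the list alone, 18 amino acid response genes fell at day 7, 23 at day 3 and 6 between them, and 12 hypoxia targets rose at day 3, where the counts over all genes tested were 16, 19, 2 and 6. Adjusted over the list alone, 14 NF-kB and inflammatory genes and 24 ribosomal protein genes rose at day 7, and 15 MYC targets rose from day 3 to day 7, against 12, 15 and 4 over all genes tested. For every called list the median, the mean and camera's direction had the same sign, and they differed in sign for 8, 4 and 6 lists that were not called at day 7, at day 3 and between them, such as hypoxia targets at day 7 (median -0.02, mean -0.06, camera up). Members beside a count of 5 or fewer that the fixed rule did not take were named after their values were seen. Their calls were not checked singly with a library left out or with the other methods.

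How far the day 3 change carried into day 7 was read across genes in b2, where both used the same 3 untreated libraries. Both times called 150 genes up and 135 down, PPIF, ANGPTL4, SOD2 and ID1 among the first and PSAT1, PCK2 and COL1A2 among the second, and 76.6% of the day 3 calls were called at day 7 in the same direction. G0S2 was the 1 gene called in opposite directions (-0.37 ± 0.07 at day 3 and 0.71 ± 0.07 at day 7). Independent lists would share 16.1 genes up and 12.9 down. Across 10586 genes, which are not independent replicates, the log2 changes had r = 0.656 and rho = 0.623, and 73.4% had the same sign. In 20 simulations of unchanged groups against the same controls the mean was r = 0.554 and 68.8%. The covariance was 0.0681 against 0.0232 simulated, a difference of 0.0449. The 3 controls are too few to be parted into 2 sets of 2 libraries, so part of the excess may come from the shared controls. Between day 3 in b2 and day 7 in b1, which had separate controls, r was 0.161 and 55.1% of 9809 genes had the same sign. The b1 values rest on 1 day 7 library.

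The authors' deposited results gave close values. With an adjusted p of at most 0.05, a log2 change of at least 0.6 in size and a mean of at least 5, read from their values, 464 genes passed at day 7 in their DESeq2 table, 219 up and 245 down, PPIF, CXCL1 and COL1A2 among them. Of the 458 tested here, 445 were called by edgeR, and the 2 sets of log2 changes had r = 0.996 across genes. At day 3, 100 genes passed and 98 were called here, and from day 3 to day 7, 120 passed and 118 were called here.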

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

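The tests of the genes that a GC and length correction ended, of the b1 and b2 cultures, of the b1 day 7 library as untreated, of doxycycline itself, of the b1 labels, of the IDH1 counts and of the induced transcript's 3′ end were chosen only after the result was seen. Results stand here because 1 sample lay far from its group or because 2 groups differed.

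IL1B and the CXCL chemokines rose more at day 7 in b1 than in b2, and 326 genes had day 7 effects that differed between the batches. GC content and length of a gene's longest transcript as the whole cause are narrowly argued against. Of the 324 genes with an annotation, 177 stayed called after a curve of both was taken out. The GC content of the counted 3′ ends was not tested and stays open. The 147 genes no longer called had a median size of 0.75 before (median SE 0.19) and 0.57 after (median SE 0.18), so part of their difference may follow GC content and length. The b1 day 7 library lay at 0.480 of the day 7 effect of the other libraries, where untreated b1 libraries reached at most 0.0766. It was still nearer to the untreated group by a bound of 0.5 written beforehand, so whether it was treated is not settled. Noise of that single library stays open, because the b2 day 7 library b2-17, tested alone against the other 3, called 227 genes (the others 1, 2 and 13), and a difference of culture or library batch cannot be told apart from it with 1 day 7 library in b1.

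PSAT1, ASNS and others of the amino acid response list fell at day 3 in b2, 19 of 30 in all. At day 7 the list's median was -0.53 in b2 and -0.02 in b1. Scaling between libraries is argued against, since with library size alone the day 3 median was -0.61 (-0.57 with TMM). A culture difference stays open: untreated b2 libraries lay above untreated b1 libraries by a median of 0.27. Its SE of 0.17 was taken over the 29 genes of the list as if independent, not over cultures. That SE alone is too wide to set against the day 3 change. Doxycycline itself may also be a cause and cannot be told apart from the induced gene, as 0 libraries had doxycycline without the induced gene. The biological explanation, an effect of the induced mutant IDH1, stays open and untested for the same reason.

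IDH1 was not called higher with doxycycline at day 3 or day 7. Mixed labels are argued against for b2: 0 of 11 b2 libraries lay nearer to the other group (treated at least 0.762, untreated at most 0.155). The b1 day 7 library lay at 0.480, nearer to the untreated group by a bound of 0.5 written beforehand. That bound was set aside for b1 only after the result was seen. The b1 day 7 library did lie above the untreated b1 libraries (at most 0.0766), but the b1 labels are not settled by this. Too few counts for a 2-fold rise are argued against by the interval's upper end of 0.42 on the log2 scale. An induced transcript without the counted 3′ end may explain the level and stays open, since the tables hold 0 columns of coding-region counts.

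Among the named genes whose day 7 effect differed (b2 minus b1, log2) were CXCL2 (-1.89), PCK2 (-1.84), CXCL1 (-1.75), CXCL3 (-1.67), PSAT1 (-1.64), CSF2 (-1.61), CXCL5 (-1.33), SERPING1 (-0.96), MT1E (-0.88), IL1B (-0.86), IFITM3 (-0.85), PHGDH (-0.76), SOD2 (-0.67), BGN (-0.57) and ANGPTL4 (1.58). Day 3 and day 7 differed at 537 genes, and G0S2, which fell at day 3 and rose at day 7, differed by 1.08. The real grouping of libraries called 1955, 372 and 537 genes at day 7, at day 3 and between them. It was the 1 split with as many among 100 drawn of 462, among 35 and among 35. The highest other split called 919, 26 and 1, so no other split drawn reached the real count. The day 7 splits ignored the batches, and no split of these libraries can exclude a chance difference between cultures. The split with 919 set 5 of the 6 untreated libraries against the rest.

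Single samples lay far from their group in 16 of 302 groups, where chance marks about 1 in 20, given here as the gap over the range of 4 libraries. In the day 7 table these were DUSP1 0.904 (b2-17 at 269 CPM, the others 199 to 206), IDH3B 0.862 and TK1 0.886 (both b2-20) and VEGFA 0.888 (b2-19). At day 3 they included CXCL1 0.877 and GARS 0.843 (both b2-12), and LSS 0.934, MT2A 0.895 and PGK1 0.835 (all b2-10). At day 7 in the other table they were ALDH1A3 0.911 and KRT81 0.907 (both b2-18), HLA-B 0.893 and LOXL1 0.954 (both b2-17), IDH1 0.880 (b2-17 at 30.2 CPM, the others 41.7 to 43.2) and TAGLN 0.981 (b2-19 at 312 CPM, the others 365 to 366).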

How the results depend on the processing

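The joined fit, the counts of the other table and all alternatives of the b1 and b2 interaction were chosen after seeing the data. Day 7 called 1955 genes and 323 without the batch term, where the difference between b1 and b2 counts as noise, and 1405 to 1970 leaving out 1 library. Day 3 called 372, 205 in the joined fit and 191 to 578 leaving out 1 library (213, 191 and 207 without untreated b2-1, b2-2 and b2-4, 229 and 228 without day 3 b2-10 and b2-12, 578 without day 7 b2-17). Day 3 to day 7 called 537, and 387 to 645 leaving out 1. Thinned to the shallowest library, the counts called 1622, 248 and 407 in these 3 comparisons. The interaction called 326, 205 with limma-voom and 195 to 687 leaving out 1 (195, 216 and 205 without untreated b1-2, b1-3 and b2-2, 687 without day 7 b2-17). IDH1 from day 3 to day 7 was 0.02, with -0.0075 in thinned counts and -0.0436 to 0.115 leaving out 1. MT-CYB at day 7 was -0.18 without the batch term, and KMT2A, called at -0.38, was 0.0817 with b2 counts of the other table and -0.17 in the joined fit (edgeR adjusted p = 0.833 and 0.535). Lists called by camera were 2, 2 and 4 with an estimated correlation at day 7, day 3 and between them, and fry called 22 and 18 at day 7 and day 3. Apart from leaving out a library, named genes kept sign and call in 1005 of 1113 values at day 7 (39 of 102 without the batch term), 426 of 452 at day 3 and 641 of 680 between them. Except where construction shows it, the cause was not tested. No paired analysis was possible because the titles give the 3 groups different sample numbers. In the table with day 3, no batch term and b2 alone are the fit already used.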

Other observations

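The test of the mitochondrial stress hypothesis was chosen only after the result was seen, and the untreated batches were compared after the data were seen. Without doxycycline, b1 and b2 astrocytes differed at 6061 of 12040 genes (edgeR, 2943 higher in b2 and 3118 lower). Of 19 glycolysis genes 17 were lower in untreated b2, with a median log2 difference of -0.91, and of 13 mitochondrially encoded genes 8 were lower and MT-CO1, MT-ND5 and MT-ND6 higher. The share of mitochondrially encoded UMIs was at most 1.58% in untreated b1 and 1.31% in untreated b2. Amino acid response genes went the other way, with 16 higher and 6 lower in untreated b2.

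MT-ND3, MT-CYB and MT-ND1 rose at day 7, and doxycycline is known to slow mitochondrial translation. A stress response to this could be expected to raise the amino acid response and ATF4 targets, but their median log2 change at day 7 was -0.41 (-0.02 in b1), and NUPR1, ALDH1L2 and PSAT1 fell. In b2 that median was -0.53, so no net rise of these targets was seen there. The fall of the list was already known when this test was chosen. Without a control for doxycycline, its effect on these targets cannot be told apart from that of the induced gene. The test therefore cannot decide the hypothesis, and other actions of doxycycline stay open too.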
